A study of Bacillus subtilis with 7 samples.

How the data were processed

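Bacillus subtilis cells were grown in LB at 37 °C to mid-log phase, RNA was extracted with hot phenol, and ribosomal RNA was removed with a Ribo-Zero kit, per the labels' protocols. RNA-seq was run on 2 libraries each of the rnjA deletion (BG880) and the rnjA rnc double deletion (BG879). PARE was run on 1 library each of these strains and of Pspac-rnjA (BG578), with a ligation protocol that selects RNA 5′ ends carrying a monophosphate, per the labels' protocols. The submitters' processing notes name CASAVA, Bowtie2, SAMtools and bedtools. Versions, settings and the genome build are not given in the sources used here.

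The expression table is as deposited by the authors and holds 1 signal value per gene and strain, where the labels give 2 RNA-seq libraries per strain. Its normalization is not given in the sources used here, and the sum of value times coding length was not equal in the strains. The same deposited table gives the authors' ratio of the double deletion to the rnjA deletion, and a p-value with 2 decimals whose test is not given in the sources used here. Each peak list was deposited by the authors per PARE library and gives a start, an end, a length, the mean coverage (called depth here) and a position label, per the file headers. The lowest depths are 102, 101 and 102, just above 100, the number in the names of the lists. A strand is not given. In the double deletion list, depth times length was a whole multiple of a single constant (1.3365) within 0.02 for 1374 of 1374 peaks, as a scaling of that library before deposit would give. No source used here states such a step. In the other lists it was whole as listed, within 0.001. Another deposited table repeats the rnjA deletion peaks with the authors' relative ratio for each, which its file does not define. Its relation to the other values was checked at 211 peaks that share at least 0.9 of their length.

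The planned tests needed values per library, and the table holds pooled values only, so no model was fitted and the authors' listed p was used as the test. A gene was called when its listed p was 0.05 or less and its value at least 1 in either strain. That filter left 2861 genes, with 293 at 0 in both strains and 1022 below the filter. Ratios are the authors', and log2 ratios were taken from them, or from the 2 values where the ratio was rounded to 0. Benjamini-Hochberg adjustment of the listed p was computed for comparison, with 0.00 read as 0.005 or as 0 over all tested genes, and as 0.005 over each list alone. Of the gene identifiers, 4173 matched the RefSeq gene table (assembly ASM904v1), which was used for current names and neighbours only.

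Gene lists were fixed before the data were examined. They are ribonucleases and RNA decay, ribosomal proteins, flagella with chemotaxis and autolysins, biofilm matrix, competence, early sporulation, cannibalism toxins, the SPbeta, skin, PBSX and ICEBs1 elements, type I toxin-antitoxin RNAs, heat shock, SigB, SigW, T-box synthetases, methionine and cysteine genes, purine, pyrimidine and tryptophan synthesis, Fur iron genes, glycolysis, stable RNAs and RNAs with known processing sites. For each list with at least 5 tested genes, the median log2 ratio was placed among 10000 random lists matched on decile of mean value, as a description of these libraries. Stable RNAs are not in the table (0 members), and the 3 type I toxin-antitoxin genes in it are listed at 0. SPbeta, skin and ICEBs1 had 0 tested genes.

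Named genes followed a rule set before the data were examined. It takes rnjA and rnc, the 10 largest rises and falls among called genes, up to 4 members per list with the smallest p in both directions, and any ribonuclease that passed. The rule's condition that replicates do not overlap could not be applied. For PARE it takes the 5 deepest peaks per library outside rRNA and tRNA and the deepest in rRNA, the 5 deepest peaks per pair that the other list lacks, the 3 largest relative depth ratios in each direction at shared positions, both outside rRNA and tRNA, and up to 8 peaks in RNAs with known processing sites. Regulatory leaders, rRNA operon parts, the relative ratios and the genes of lost peaks were chosen after their values were seen.

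Peaks were compared by overlap of at least 1 nt, with Wilson intervals at 95%, and with overlaps after random shifts of all positions around the chromosome. Position labels give coding gene ends by coordinate and not by strand, so start and stop codon ends were assigned from the strand in the expression table. Depth ratios used peaks matched 1 to 1 and were taken relative to the median ratio. The depth of the libraries beyond their listed peaks is unknown. Sequence context at peaks was not analysed, since no genome sequence was used here.

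The alternatives tried were quantile normalization, equal totals, other pseudocounts, thresholds and filters, rotation of lists around the gene order, stricter depth limits, rRNA and tRNA left out, depth times length in place of depth, and other overlap rules. The list statistic was tested on simulated data before use. With the 2861 genes of the RNA-seq comparison shuffled, 4% of 200 lists of 20 genes lay outside the central 95% of random lists, against 61% with a planted shift of 0.5 on the log2 scale and 99% with a shift of 1. Shuffling breaks up operons, so the 4% holds for lists of unrelated genes and not for lists whose members share operons. The overlap step found all 1208 regions planted among 2416 in each of 20 repeats. The planted regions were exact copies, so this checks the computation only. A mean of 1262.1 regions were found per repeat, those beyond 1208 through overlap with randomly placed regions. No per-sample column was left without a sample (0). Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.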

Results

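Total RNA of Bacillus subtilis, grown in LB at 37 °C to mid-log phase and depleted of ribosomal RNA, was measured in 7 libraries from 3 strains. The rnjA deletion strain lacks RNase J1, the exonuclease that degrades RNA from a 5′ monophosphate. The rnjA rnc double deletion strain also lacks RNase III, which cuts double-stranded RNA. In the Pspac-rnjA strain, RNase J1 is made from a promoter that an inducer controls, and whether inducer was added is not given in the sources used here. PARE, a sequencing method that ligates an adaptor to RNA 5′ ends with a monophosphate, was run on 1 library of each strain. RNA-seq was run on 2 libraries of each deletion strain, of which the deposited table gives 1 value per strain. No difference below therefore has a replicate check of its own. The RNA-seq table gave a value for 3883 coding genes and listed 293 more at 0 in both strains. The peak lists held 2416 peaks for the rnjA deletion, 1374 for the double deletion and 1255 for Pspac-rnjA. Read totals were not part of the files, so the depth of each library is known only through its peaks. The lowest mean depth of a listed peak was 102, 101 and 102 in the same order, and the medians were 222, 270 and 187.

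The RNA-seq libraries asked how loss of RNase III, on top of loss of RNase J1, changed the level of each mRNA. The gene for RNase III, rnc (BSU15930), fell from 15.35 to 0.40 in the authors' deposited table, a ratio of 0.03 with a listed p of 0.00. The gene for RNase J1, rnjA (BSU14530), is deleted in both strains and stood at 0.61 and 0.82, with a listed p of 0.59 in the authors' deposited table. Among other ribonuclease genes, rnmV, whose product matures 5S rRNA, fell to a ratio of 0.46 in the authors' deposited table. The gene rph, for the exonuclease RNase PH that trims tRNA 3′ ends, rose to 1.79 there. The gene for RNase Y, named ymdA in the table, had values of 404.62 and 493.46 and a listed p of 0.26 in the authors' deposited table. The list of ribonucleases and RNA decay genes had 1 member higher and 2 lower among 21 tested, and none passed when adjusted over the list alone (0). Its median log2 ratio was -0.29, at percentile 27.1 of random lists, and 0.00 with the totals of both strains set equal.

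On the authors' ratios, genes of swimming cells had the highest median of the lists. With a pseudocount of 10 the methionine and cysteine list stood higher, at 0.62. The genes fliE, fliG, fliH, fliI, fliJ, ylxF, fliK and flgD, neighbours in the operon for the flagellar basal body and its export apparatus, rose by ratios of 28.39 to 49.33 in the authors' deposited table. Their values in the rnjA deletion were only 0.12 to 0.29 there, so they passed the filter through the double deletion alone. From the same operon flgC rose 15.69-fold, and fliS, for the chaperone of the filament protein, rose 4.25-fold in the authors' deposited table. In 53 tested genes of flagella, chemotaxis and autolysins, 23 rose and 1 fell, and the median log2 ratio was 3.53 (percentile 100). The exception was lytE, for a cell wall hydrolase, which fell from 151.22 to 62.03 in the authors' deposited table. The size of the flagellar median rests on low values, and it was 1.95 with a pseudocount of 1 and 0.48 with 10. The biofilm matrix list moved the other way, with all 20 tested genes lower and a median log2 ratio of -1.23 (percentile 0). It includes yuaB, now named bslA, for the surface layer protein of the biofilm (ratio 0.20), and epsL, epsA and epsB of the exopolysaccharide operon (0.37, 0.44 and 0.45 in the authors' deposited table). Adjusted over the list alone, 19 flagellar genes and 20 matrix genes passed. In both lists the direction of the median was the same under quantile normalization, equal totals and the pseudocounts tried.

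Genes of sulfur and nucleotide supply also moved as lists. Genes under the S-box riboswitch or the cysteine regulator CymR had a median log2 ratio of 2.60 (percentile 100), with 11 of 19 higher and none lower (0). They include cysC, sumT, sirB and sirC of the sulfate assimilation operon, at 13.84, 10.85, 2.85 and 2.57 in the authors' deposited table. The methionine salvage gene mtnB rose 27.53-fold, from a low value of 0.56, in the authors' deposited table. Purine biosynthesis genes had a median of 1.56 (percentile 99.9), with 7 of 13 higher, among them purN (3.85), guaB (3.23) and purL (4.52 in the authors' deposited table). Of these, purN and purL rose from low values of 0.31 and 0.38 in the authors' deposited table. The list had 2 members lower, guaA of the GMP branch at 0.31 and purA of the AMP branch at 0.49 in the authors' deposited table. All 10 pyrimidine genes lay below 0 on the log2 scale in the plot of gene lists, with a median of -1.06 (percentile 0.995, or 4.57 with a pseudocount of 10), and 0 passed the threshold. Adjusted over the list alone, 8 sulfur genes, 8 purine genes and 0 pyrimidine genes passed.

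Ribosomal protein genes were lower as a list. In the ribosomal protein list, 31 of 54 genes fell, with rplN, rplF and rpsB at 0.45, 0.47 and 0.48 in the authors' deposited table. Its median log2 ratio was -0.97 (percentile 0), and 24 genes passed when adjusted over the list alone. The median kept its sign under equal totals and the pseudocounts tried, and under quantile normalization it was -0.30 at percentile 3.02. The only riser of the list was the gene named rpsA in the table, now named rpfA, at 2.34 in the authors' deposited table. Of 17 glycolysis and sugar uptake genes 10 fell, with a median of -0.74 (percentile 8.68, or 0.24 under quantile normalization) and 2 adjusted over the list alone. They include the glucose transporter gene ptsG (0.26), the phosphotransferase genes ptsI and ptsH (0.40 and 0.44) and tpiA (0.53 in the authors' deposited table). The gluconeogenesis genes gapB and pckA both fell to 0.17, and the arginine catabolism genes rocA and rocG to 0.12 and 0.14 in the authors' deposited table. After rnc, the steepest fall was in ysbB, now named pftB, for a pyruvate uptake protein, from 204.45 to 9.12 in the authors' deposited table. The transport genes dtpT and thiT and the gene ydeD fell to 0.23, 0.16 and 0.13 in the authors' deposited table.

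Stress and differentiation lists gave smaller counts. SigB general stress genes had a median log2 ratio of 1.37 (percentile 100), with 3 of 31 higher (opuE, dps and rsbU at 6.40, 2.39 and 1.70 in the authors' deposited table). Genes of the PBSX prophage had a median of -0.81 (percentile 0, or 3.71 when the list was rotated around the gene order), with xkdH, xkdO and xkdF lower. Cannibalism toxin genes had a median of 1.68 (percentile 96.5, or 98.8 with a pseudocount of 1), with sdpA higher at 3.21 in the authors' deposited table. In the competence list comFB rose to 1.96, and in the early sporulation list spoIID rose to 3.53 while spoIIE fell to 0.38 in the authors' deposited table. Their medians were 0.34 (percentile 72.3, or 99.9 with a median of 0.84 without the filter on value) and 0.16 (percentile 63.4), the latter -0.06 under quantile normalization. Medians of the heat shock, SigW envelope stress, T-box synthetase and Fur iron lists were 0.00, -0.14, -0.07 and -0.40, at percentiles 83.3, 56.1, 83.5 and 5.94, and the first 3 were 0.29, 0.15 and 0.22 with totals set equal, while without the filter the Fur list stood at percentile 1.12. From these lists htpG, sigW, ydbT, tyrS and fhuC fell, and yceG, yceH and serS rose. Adjusted over the list alone, 2 early sporulation genes and 1 cannibalism gene passed, against 0 in the SigB, PBSX, competence, heat shock, SigW, T-box and Fur lists. The tryptophan operon had 1 tested gene, with a log2 ratio of 0.36. Of mRNAs with known processing sites, cggR fell to 0.25 and infC to 0.70 in the authors' deposited table. The methionine synthesis gene yjcI rose to a ratio of 22.79, from a low value of 0.2 to 4.45 in the authors' deposited table. In that list 1 of 12 was higher and 4 were lower, with a median of -0.46 (percentile 30.0; without the filter 0.07, percentile 83.9) and 0 adjusted over the list alone.

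**Figure D1:**
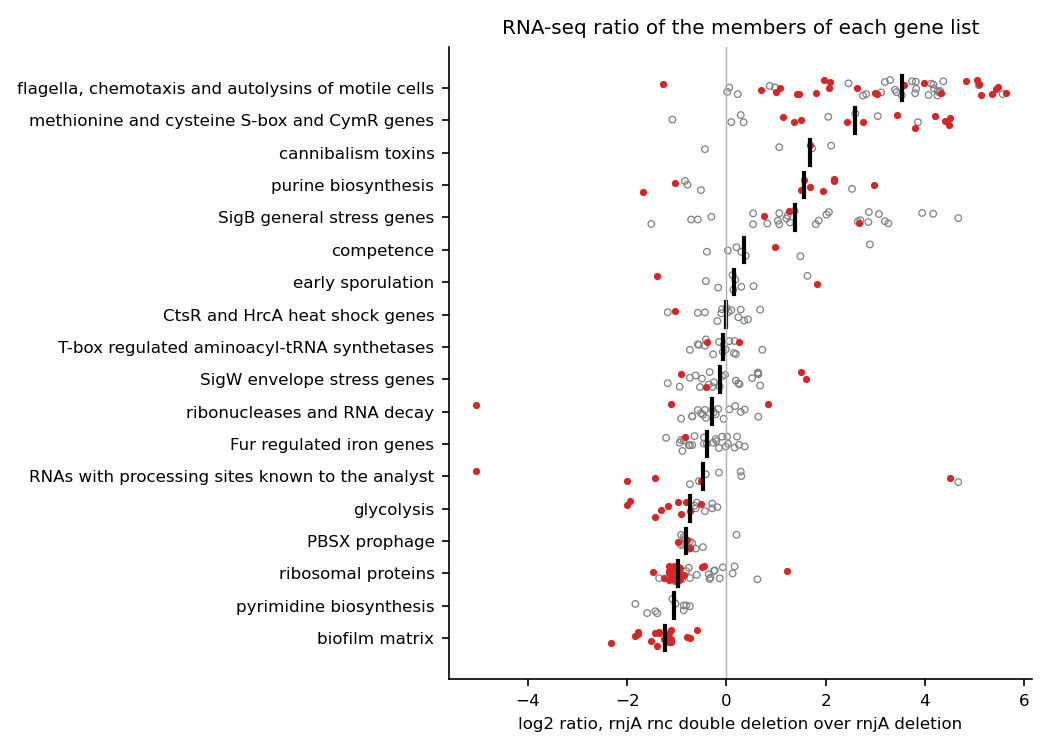
Log2 ratio of the double deletion to the rnjA deletion from the authors' deposited values, for each tested member of 18 gene lists. Filled points passed the listed p of 0.05, open points did not, and bars mark medians, from 3.53 for flagella to -1.23 for the biofilm matrix.

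Across the table, 814 of 2861 genes with a value of at least 1 in either strain passed the authors' listed p of 0.05 or less. Of these 358 were higher and 456 lower in the double deletion, where chance with rounded p would give 157. A change of at least 2-fold was seen in 247 higher and 213 lower genes. The largest ratio, 640.96 in the authors' deposited table, belonged to the teichoic acid gene ggaB and rests on a value of 0.01 in the rnjA deletion strain. The median ratio was 0.94 (log2 -0.09), and setting the totals of both strains equal moved the median by 0.29. With that shift the 2-fold genes were 295 higher and 88 lower, a share of 77.0% higher against 53.7% on the deposited scale. The listed p was taken as unadjusted, which the sources used here do not state. The 157 given for chance and the adjusted counts rest on that reading. After Benjamini-Hochberg adjustment 0 genes passed when a listed 0.00 was read as 0.005, and 138 when it was read as 0. Of the 18 lists with a percentile, 8 lay outside the central 95%, where lists of unrelated genes would give 0.9 by chance. Many members of these lists share operons, so their ratios are not independent, and more than 0.9 lists could lie outside by chance. Rotation around the gene order, which keeps neighbours together, moved the PBSX list from percentile 0 to 3.71. These percentiles describe these libraries only.

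The PARE libraries asked where 5′ monophosphate ends accumulated in each strain. In the rnjA deletion, the deepest peak outside rRNA and tRNA lay in pyaA, an attenuator leader of the pyrimidine operon, with a mean depth of 100900. The next were at the stop codon ends of yqgA, of ymdA, of murAA for a cell wall synthesis enzyme, and of glpP for the glycerol regulator (57702, 49437, 48243 and 45703). In the double deletion the ymdA peak was deepest (50439), followed by the stop codon end of rnjB for RNase J2 (49549), pyaA (38474), the region between glpP and glpF (32579) and the ribosomal protein gene rplL (29207). In Pspac-rnjA the yqgA peak led (7746), followed by a region between yddM and yddN (7444), murAA (6579), rnjB (4130) and the ribosomal protein gene rpmA (4025). Depths are the authors' mean depth over each peak, per the file headers.

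Peaks inside coding genes made up 1154 of 2416 in the rnjA deletion (47.8%, 95% Wilson interval 45.8% to 49.8%). They made up 418 of 1374 (30.4%, 28.0% to 32.9%) in the double deletion and 550 of 1255 (43.8%, 41.1% to 46.6%) in Pspac-rnjA. Peaks over a stop codon end were 606, 468 and 236, or 25.1%, 34.1% and 18.8%. Start codon ends held 101, 35 and 57 peaks, and regions between genes held 329, 262 and 181. These shares depend on depth, because the rnjA deletion peaks inside genes were shallow, with a median depth of 160 against 386 at stop codon ends. Among the 1252 deepest rnjA deletion peaks outside rRNA and tRNA, as many as the double deletion list holds, 34.4% lay inside genes, against 33.4% in the double deletion. Peaks in rRNA or tRNA held 31.4% of the listed depth times length in the rnjA deletion, 67.1% in the double deletion and 65.8% in Pspac-rnjA. The intervals cover counting error only.

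Around ribosomal RNA the peaks of the double deletion differed in depth from overlapping rnjA deletion peaks, in a direction that depended on the part of the operon. Bacillus subtilis has 10 rRNA operons, and RNase III cuts the RNA stalks on either side of 16S and 23S. Before 16S, the double deletion peak was deeper than the overlapping rnjA deletion peak in 10 of 10 operons, by 3.39-fold (rrnE) to 210-fold (rrnA), with a median of 52.7. In rrnA the depths were 551 in the rnjA deletion, 115952 in the double deletion and 771 in Pspac-rnjA. In rrnW and rrnE the double deletion peak carries the label of the tRNA gene ahead of the operon. At the 3′ end of 23S the double deletion was deeper in 10 of 10 operons, by 3.52-fold to 39.6-fold (median 12.4), and rrnB held the deepest peak of its list (202219). Peaks inside 16S or 23S went the other way, deeper in the double deletion in 0 of 10 operons (median ratio 0.431), as did 5S in 0 of 4 (0.409). In the spacer between 16S and 23S, where the rnjA deletion and Pspac-rnjA had their deepest rRNA peaks (106029 in rrnJ and 63752 in rrnB), the deepest peak was deeper in the double deletion in 3 of 10 operons (median ratio 0.826), a direction that turned when all spacer peaks were summed. Depth times length there was 1.39 times higher in the double deletion, over 1182 nt against 1321 nt, with mean depths of 86724 and 55760 per covered nt. None of these operon ratios is relative to the median of shared positions, where the rnjA deletion was deeper by 1.47. On that relative scale all of them would stand higher for the double deletion, and the spacer count of 3 would rise.

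Peaks assigned to the part before 16S had a median depth of 47395 in the double deletion and 789 in the rnjA deletion. The double deletion had 10 such peaks in 8 operons, since rrnE and rrnW fall under tRNA labels, and the rnjA deletion 12 in 10 operons. In the rnjA deletion and Pspac-rnjA some of these peaks carry the label of the 16S end. At the 3′ end of 23S, depth times length summed over 10 operons was 7.19 times higher in the double deletion, over 551 nt against 487 nt, with mean depths of 100114 and 15756 per covered nt and median peak depths of 90449 and 4482. In Pspac-rnjA the medians were 563 before 16S and 5381 at the 3′ end of 23S. The first of these includes peaks at the 16S end itself, such as 616 in rrnO and 2919 in rrnB. The medians before 16S are therefore not taken at the same sites in each library. The operons are near-identical, so reads cannot be assigned to a single copy with certainty, and each library is a single sample.

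**Figure D2:**
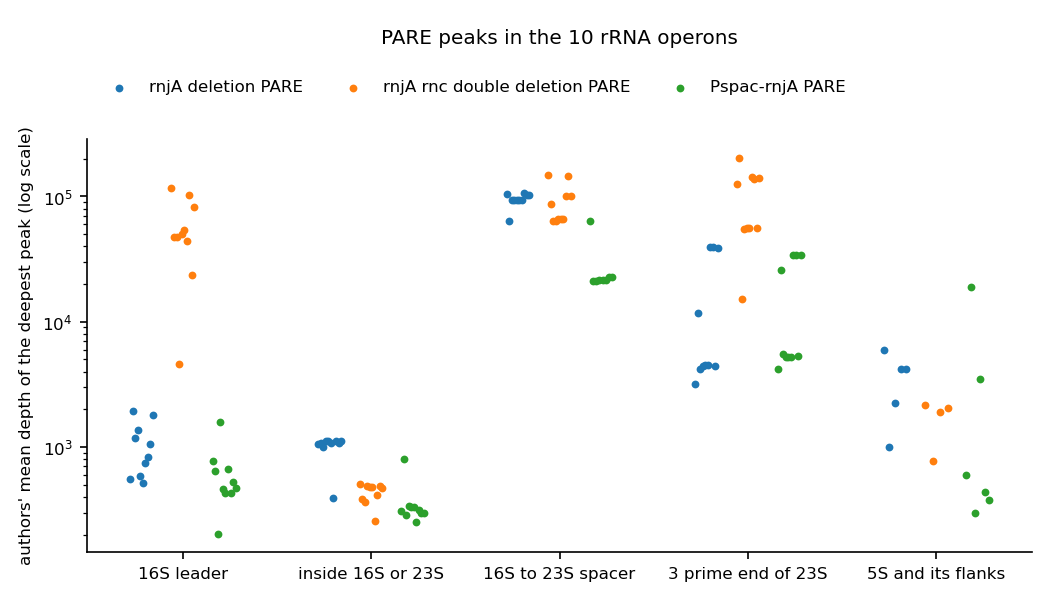
Authors' mean depth (log scale) of the deepest PARE peak in each part of each rRNA operon, 1 point per operon, coloured by library. Before 16S the double deletion and Pspac-rnjA points are instead peaks that overlap the rnjA deletion peak. The double deletion peak in rrnE and rrnW, and the Pspac-rnjA peak in rrnE, carry a tRNA label. The double deletion points before 16S and at the 3′ end of 23S sit above those of the rnjA deletion in 10 of 10 operons when compared operon by operon.

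The overlap of the lists asked which 5′ ends were listed with and without RNase III. Outside rRNA and tRNA, among the deepest rnjA deletion peaks that the double deletion did not list were those between yutG and yutF (2184), between ykzW and the polyamine gene speA (1553), and at the stop codon end of the phosphate-binding protein gene pstS (1311). The others of the deepest 5 lay between yrzA and yrrS (1267) and at the stop codon end of the sporulation gene spoVD (1017). The double deletion listed peaks between epsC and epsB (1626), between yoaD and the S-box leader mswF (614) and in the methionine salvage gene mtnW (586) that the rnjA deletion did not. Peaks at gltD for glutamate synthase (582) and between bdhA and ydjM (532) completed its deepest 5. Of the rnjA deletion peaks, 1206 of 2416 shared at least 1 nt with a double deletion peak (49.9%, 47.9% to 51.9%), against a mean of 4.70% after random shifts. In the other direction 1282 of 1374 were shared (93.3%, 91.9% to 94.5%). A peak missing from a list is not the same as no cleavage, since the authors' limits for listing are not given in full in the sources used here.

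Pspac-rnjA shared 982 of its 1255 peaks with the rnjA deletion (78.2%) and 651 with the double deletion (51.9%). The reverse shares were 40.2% of the rnjA deletion peaks and 48.0% of the double deletion peaks. Peaks found in neither other list numbered 855 in the rnjA deletion, 86 in the double deletion and 266 in Pspac-rnjA. Outside rRNA and tRNA, the deepest rnjA deletion peaks without a Pspac-rnjA counterpart were at yhdY (5308), the pyrimidine salvage gene pdp (4047) and ywsB (3002), between yvcI and the thioredoxin reductase gene trxB (2938) and between yhbF and the kinase gene prkA (2705). For the double deletion they lay between sacP and ywcJ (3068), at yngC (2524), in the T-box leader tboV (2490), in pyrK of the pyrimidine operon (2225) and at rsbX (2199). Pspac-rnjA in turn listed the bacteriocin immunity gene sunI of the SPbeta prophage (1304), yqdB of the skin element (626), yqgY (550), a region between yolA and yokL, also of SPbeta (546), and the glycolysis gene pgk (485), none of them in the rnjA deletion list. Against the double deletion its deepest were sunI, atpC for an ATP synthase subunit (987), the purine riboswitch gswC (748), yutF (747) and the elongation factor gene fusA (650). In both deletion strains 189 of 190 SPbeta genes and 62 of 62 skin genes were listed at 0 by RNA-seq. A peak absent there may thus mean an absent region and not a lost end.

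At 1062 positions matched 1 to 1, the rnjA deletion was deeper than the double deletion by a median ratio of 1.47 (quartiles 1.02 to 2.22). Peaks at a shared position can differ in length, so each fold below, relative to the median and for positions outside rRNA and tRNA, is given by depth and then by depth times length. The region between ywmA and atpC was deeper in the rnjA deletion (20.6 and 75.8), as were murAA (9.07 and 10.8) and the higher-coordinate end of the T-box leader tboT (7.69 and 9.23). Deeper in the double deletion were the region between sacP and ywcJ (14.5 and 20.3), pyrK (13.3 and 20.5) and the lower-coordinate end of tboT (11.4 and 3.82). In all, 48 positions, rRNA and tRNA included, lay at least 4-fold from the median, and 114 by depth times length. Against Pspac-rnjA, the median ratio was 1.99 for the rnjA deletion (750 positions) and 1.94 for the double deletion (552 positions). The rnjA deletion was relatively deeper at pyaA (58.6 and 56.7), yjlA (22.4 and 23.8) and yocH (17.9 and 40.1), and Pspac-rnjA at adk (7.99 and 48.0), between ybzG and the initiation factor gene infA (7.97 and 32.9) and in groEL (6.76 and 14.9). The double deletion was relatively deeper at yjlA (25.1 and 30.5), pyaA (22.96 and 27.2) and the T-box leader tboG (19.2 and 18.5), and Pspac-rnjA at the leader qswA (11.9 and 33.3), between gswC and pbuG (9.13 and 17.1) and in fusA (8.63 and 148).

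**Figure D3:**
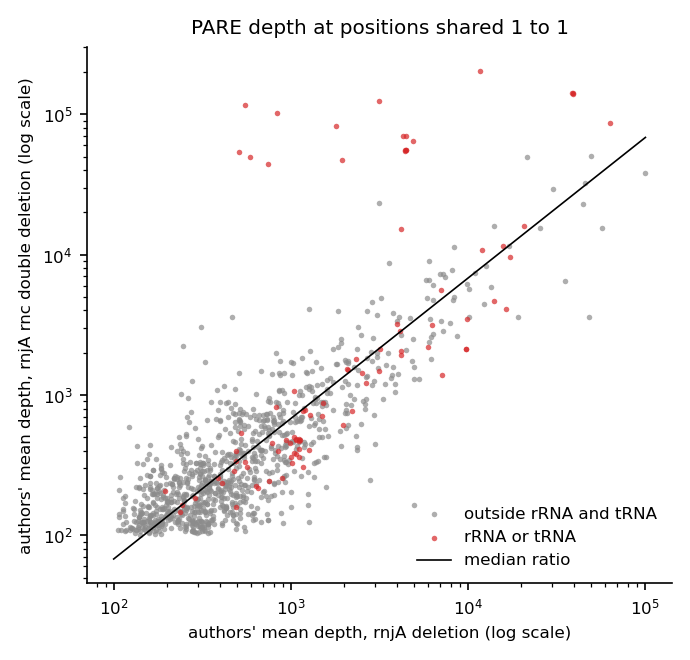
Authors' mean PARE depth (log scales) at 1062 positions matched 1 to 1 between the rnjA deletion and the double deletion, 1 point per position, with rRNA and tRNA positions in red. The line marks the median ratio of 1.47.

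Known processed RNAs had peaks in several libraries. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, had its deepest peaks at both ends in the rnjA deletion (5624 and 5392). The double deletion listed a single ssrA peak (1433), and Pspac-rnjA had 513 and 2928 at the same ends. The glycolysis gene gapA, cut from its operon partner cggR by RNase Y, had a stop codon end peak of 9847 in the rnjA deletion. The double deletion had an overlapping peak of 6154, labelled between pgk and gapA, and Pspac-rnjA had 753 at the stop codon end. The signal recognition particle RNA scr had depths of 2280, 1585 and 626 in the same order. A peak over the whole ribosomal protein gene rpsO was 1593 deep in the rnjA deletion and 424 in Pspac-rnjA. The double deletion listed shorter peaks there, of 1141 at the stop codon end and 405 inside the gene. Over hbs, for a nucleoid protein, depths were 1127 in the rnjA deletion, 649 in the double deletion and 822 in Pspac-rnjA. Inside pnpA, for the exonuclease PNPase, the depth was 1312 in the rnjA deletion and 1070 in the double deletion. The rnc mRNA had peaks in the rnjA deletion (724 at its stop codon end) and in Pspac-rnjA (260), and none in the double deletion list, where the gene is deleted.

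Regulatory leaders carried deep peaks in both deletion strains. T-box leaders, which read tRNA charging ahead of amino acid genes, held 20, 23 and 20 peaks in the rnjA deletion, the double deletion and Pspac-rnjA, with median depths of 902, 864 and 232. Of 15 T-box peaks matched 1 to 1, 10 were deeper in the rnjA deletion and 5 in the double deletion, or 7 when taken relative to the median of all shared positions. Among those 5, the glycyl T-box leader tboG had depths of 3173 in the rnjA deletion and 23171 in the double deletion, against 621 in Pspac-rnjA. The T-box leader tboX had depths of 358 and 477 at its ends in the rnjA deletion and a single peak of 3258 in the double deletion. S-box leaders held 9, 9 and 2 peaks, with median depths of 246, 411 and 441. The purine riboswitch gswB had depths of 17137 and 11605 in the deletion strains. These leaders were chosen after their values were seen.

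The authors' deposited table also gives a relative ratio for each rnjA deletion peak. Across 211 closely matched peaks it tracked the depth ratio, rnjA deletion over double deletion, multiplied by the RNA-seq ratio, double deletion over rnjA deletion (r 0.921 across peaks, which are not independent replicates). These 211 peaks carry labels of coding genes, so rRNA peaks were not part of this check. The definition of the relative ratio is not given in the sources used here. Over all peaks it ran from 0.0144, before 16S in rrnJ, to 220, in the spacer of rrnH, in the authors' deposited table. Before 16S it was not low in every operon, at 9.21 in rrnE and 0.989 in rrnO. At the deepest such peak of the other operons it lay between 0.0144 (rrnJ) and 0.505 (rrnW). It was 12.2 and 30.0 at second peaks assigned there in rrnJ and rrnW in the authors' deposited table. For the deepest spacer peak of each operon it lay between 3.08 (rrnO) and 220 in the authors' deposited table. In the rrnH spacer the listed depths were 94453 in the rnjA deletion and 65916 in the double deletion. That difference is far smaller than the relative ratio, and the sources used here do not explain the gap. Outside rRNA and tRNA it was highest at 2 shallow peaks, between cysC and sumT (152 at a depth of 204) and in priA (150 at a depth of 124 in the authors' deposited table). Among peaks with a depth of at least 500 it was highest at pstS (24.9), mraW of the cell division operon (17.8), the glutamine synthetase repressor gene glnR (17.5) and the region between bglP and yxxE (15.9 in the authors' deposited table). The lowest outside rRNA and tRNA, at any depth, were pyrK (0.0657), the region between dnaA and dnaN (0.118) and the thiamine leader tswC (0.153 in the authors' deposited table). The median over 2412 peaks was 2.24, with 85 peaks at 10 or more, of which 20 were in rRNA or tRNA, and 333 under 1. Peaks inside coding genes had a median of 2.94 and stop codon ends 1.70.

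The last comparison asked whether mRNAs that lost a peak in the double deletion also changed in level. Among the genes of the deepest lost peaks, ysbB, nagP (BSU07700), des and gapB had ratios of 0.04, 0.34, 0.24 and 0.17 in the authors' deposited table, all past the listed threshold. Others, such as pstS (0.59), spoVD (0.51), the RNA helicase gene cshA (0.62) and glnR (0.60 in the authors' deposited table), did not pass. The 643 tested genes with at least 1 peak absent from the double deletion list had a median log2 ratio of -0.51, below every random list of matched expression (percentile 0), and 31 were higher against 164 lower. The 423 tested genes whose peaks were all kept had a median of -0.06 (percentile 100), with 44 higher and 53 lower. The random lists matched to these sets had medians of -0.25 for lost and -0.20 for kept peaks. With totals set equal, the median of the genes with a lost peak was -0.23. That setting shifts all genes alike, so the percentile of 0 could not change. A lower mRNA level lowers PARE depth by itself, so the lists do not separate fewer cuts from less mRNA.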

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

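The alternatives with a p of 0.01, Benjamini-Hochberg adjustment, a pseudocount of 1, equal totals, reciprocal overlap, depth times length and rotation, all alternatives for gene lists except quantile normalization, and both scalings of the genes with lost peaks, were chosen after seeing the data. Of 532 comparisons with an alternative 483 were counted as unchanged, by rules of unlike strictness. For named genes the rule was direction alone, which 325 comparisons kept. For gene lists it was the position inside or outside the central 95%, with 101 kept and 7 moved. Equal totals shift all genes alike, so that setting could not move any of the 18 lists or the percentile of the genes with a lost peak. Among the other results 57 were unchanged and 42 moved. Of 65 named genes 0 changed direction under quantile normalization, equal totals or pseudocounts of 0.1, 1 and 10. A pseudocount cannot change the direction of a ratio. Without a filter 926 genes passed, 441 higher and 485 lower. At a listed p of 0.01 the count was 329 (157 higher, 172 lower), and 213 at 2-fold, a stricter limit by construction. With Benjamini-Hochberg adjustment it was 0 (0 higher, 0 lower) with 0.00 read as 0.005, and 138 (68 higher, 70 lower) with 0.00 read as 0, so rounding of the listed p decides it. The 2-fold count of 460 became 286 with a pseudocount of 1 and 73 with 10, which shrink ratios of low values, and was 383 to 525 under the other settings apart from the stricter p. The log2 ratio of rnc ranged from -1.29 to -5.41. Between 7 and 10 lists lay outside the central 95%, against 8. At 2 times the lowest depth the rnjA deletion, double deletion and Pspac-rnjA lists held 1307, 866 and 572 peaks, and at 5 times 618, 447 and 215. The share of rnjA deletion peaks in the double deletion list was 78.2% and 96.9% at these depths, 47.7% without rRNA and tRNA and 39.7% with reciprocal overlap of 50%, and in the Pspac-rnjA list 55.9%, 79.3%, 37.0% and 25.8%. For the double deletion peaks, the shares were 97.6% and 98.7% in the rnjA deletion list, with 69.8% by reciprocal overlap. In the Pspac-rnjA list they were 61.0% and 76.7%, with 43.3% without rRNA and tRNA and 33.5% by reciprocal overlap. Pspac-rnjA shares were 89.7% and 93.5% in the rnjA deletion list, with 49.7% by reciprocal overlap, and 71.9% and 88.8% in the double deletion list, with 36.7%. The depth limits were applied to the list whose share is given and not to the other list, so deep peaks were compared with full lists. On that basis shares rose with depth in each direction, and a distance of up to 5 nt moved no share outside its interval. With scaling by total depth, 111 positions in place of 48 lay 4-fold from the center for the deletion strains. By depth times length, 114 did, and 224 in place of 107 for the rnjA deletion and Pspac-rnjA, as unequal peak lengths add to the spread. The median of genes with a lost peak was -0.23 to -1.64, the latter from 11 genes with deep peaks. No paired analysis was possible because the table holds 1 value per strain, although the labels number the RNA-seq replicates 1 and 2 in both strains. For the same reason limma without trend, the replicate block, leaving out each library and an estimated inter-gene correlation were not run. Size factors and count models were not run because the table holds no counts. Leaving out stable RNAs was not run because the table holds coding genes only, and sequence context was not run. Depth limits what the lists show, since no peak under a mean depth of about 100 or a length of 25 nt is listed.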

Other observations

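The tests in this part were chosen after the results were seen. Genes of 3 mobile elements were listed at 0 in the RNA-seq table, with 1 exception. SPbeta, a prophage that carries the sublancin bacteriocin genes, had 189 of 190 genes listed at 0 in both deletion strains, with yomL at 0.06 in the rnjA deletion and 0.28 in the double deletion in the authors' deposited table. The skin element, which interrupts the sigK gene until sporulation, had 62 of 62 at 0, and the conjugative element ICEBs1 had 25 of 25. In PBSX, a defective prophage, 0 of 32 were at 0. The Pspac-rnjA PARE list held 6 peaks in SPbeta, among them sunI at a depth of 1304, and 5 in skin, among them yqdB at 626.

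For the 276 of 277 genes at 0, low expression would leave many other genes at 0 too, but only 0.436% of the genes outside the 3 regions were (17 of 3899). An alignment that left the regions out of all the peak lists is argued against by the 11 Pspac-rnjA peaks there. Of the peaks outside rRNA and tRNA, 0.0284% of the 3525 in the deletion strains lay in SPbeta or skin (1 peak, upper limit 0.161%), against 1.01% of 1089 in Pspac-rnjA (0.565% to 1.80%). This is consistent with strains that lack SPbeta and skin, so that the deletion strains may differ from Pspac-rnjA in more than the ribonuclease genes. For ICEBs1 no list held a peak, and whether it is absent stays open. Genotypes beyond the ribonuclease genes are not given in the sources used here, and no biological explanation was tested.

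The double deletion list was shorter, with 1374 peaks against 2416. A scaling of its depths by the constant that makes them whole numbers would have raised them, and dividing it out leaves 1135 peaks above the lowest rnjA deletion depth, so such a scaling would work against a shorter list. Lower mRNA levels as the whole cause are argued against by genes with an RNA-seq ratio of at least 1, where 39.9% of 531 rnjA deletion peaks were absent (35.8% to 44.1%), compared with 64.5% of 1314 where the ratio was lower. A depth lower by 1 factor outside rRNA and tRNA may explain the makeup of the list: the 1252 deepest rnjA deletion peaks hold 34.4% inside coding genes, within the 30.8% to 36.0% of the double deletion. Loss of cuts by RNase III at single sites stays open, since 73.6% of those 1252 peaks were in the double deletion list.

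Peaks before 16S and at the 3′ end of 23S were deeper in the double deletion in 10 of 10 operons. More rRNA reads of every kind would deepen peaks inside 16S and 23S too, and their median ratio was 0.431. Dividing the double deletion depths by that constant leaves the lowest ratio of any operon at 2.54. Reads placed in other copies of the operons would leave the sums over all copies alike, and the smaller of the sum ratios was 7.19, over 551 nt against 487 nt covered. The rnc deletion, the difference the labels name, could account for the change in depth at these overlapping peaks. With 1 library per strain its effect cannot be separated from other differences between the libraries.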
